A study of Mus musculus with 18 samples.

How the data were processed

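RNA was measured by sequencing in 8 libraries of cultured B16F10 mouse melanoma cells and 10 libraries of B16F10 tumours, each with a lentiviral shRNA against Hgs (shHrs) or a scrambled control (shCTL). Per the labels' protocols, libraries were made with a NEBNext Ultra kit and read as pairs on an Illumina HiSeq. STAR 2.4.0h2, DESeq and the mouse build mm10 are named per the submitters' processing notes. The counting tool, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. The deposited table held raw counts per gene symbol, as whole numbers with no normalization, for 23453 symbols in 18 libraries. Every column of the table was used. Total counts ran from 17.6 M to 27.7 M per library (M, mega), which set the precision of each gene's value. Libraries of a group differed from each other by more than sampling noise, with chi-square values per degree of freedom from 14.5 to 220, against 1 for sampling noise alone, so each was kept as its own replicate. Per the labels, the cells had 4 and the tumours 5 biological repeats.

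All statistics were computed from those counts in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 with its defaults (minimum count 10), and libraries were scaled by TMM. Groups with shHrs were compared with shCTL by edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The cultured cells were fitted with batch as a term. Each batch was also tested in a fit of the 8 cultures with a mean per batch and treatment, which gave the difference between the batches' effects as an interaction. The 10 tumours were fitted on their own. The difference between the effect in tumours and the mean effect in the cultures was tested in a fit of all 18 libraries with a mean for each of the 6 groups. A direct comparison of levels in tumours and cultures was not tested, because kind of sample and sequencing run could not be separated. Standard errors are those implied by the fold change and its F statistic. CPM are those of edgeR's cpm function on TMM-scaled library sizes, and log2 CPM carry a pseudocount of 2, or of 0.5 in the permutation tests of Xist.

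A set of 41 gene lists with 831 genes was written before the data were examined, as were the tests, their samples and covariates, the rule for named genes and the first set of alternatives. The lists covered pathways, protein complexes, signs of RNA quality and markers of the cell types that a tumour piece can hold. Of their symbols, 12 were matched through an older symbol and 23 were absent from the table. The table had 0 mitochondrially encoded genes, so the list of mitochondrially encoded transcripts was not tested. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists. Camera with the correlation estimated for each list and fry, which tests whether a list's genes move to one side on balance, were run beside it. Counts given as adjusted over the list alone use a Benjamini-Hochberg adjustment over that list's genes. It makes no correction for the number of lists. Genes named only as passing in this way did not pass the threshold over all genes tested. Levels of single markers and lists in tumours were compared by two-sided exact permutation tests over 252 splits, where the smallest possible p is 0.00794. For a difference fitted beside a marker level, labels were permuted with that level held fixed. Such a permutation p is not exact where the marker level differs with the treatment.

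Genes were named by a fixed rule. It took Hgs, the 8 rising and 8 falling genes with the largest fold changes among those past the threshold with a mean log2 CPM of at least 1 and a direction shared by both batches or, in tumours, no overlap between the groups. It also took up to 4 changed members of each called list or list with 3 or more changed members, and 22 genes of interferon signalling, antigen presentation, immune cells, protein stress and ESCRT whatever their result. For differences between effects it took the 4 largest in each direction. Symbols of predicted genes were left out, and some genes that the rule took are not reported here. The fit of both culture batches called 0 genes, so the rule was applied to the calls of batch 2, a step chosen after the data were seen, and the largest genes were thus limited to those with the same sign in batch 1. Other genes, such as Trim25 in cells, Cd9 and S100b in tumours, Acta1, and list members named for batch 1 or as passing over the list alone, were picked outside the rule after the data were seen. Positions are those of GENCODE release 21 for mouse on GRCm38, the assembly of mm10.

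The procedures were tested on simulated counts with known changes. In simulations of the fit of both culture batches, 11.0% of genes changed 2-fold and 82.0% of genes changed 4-fold were called among 12495 genes. For batch 2 the shares were 6.00% and 72.0% of 12727 genes, for the tumours 75.0% and 98.0% of 13087 genes, for tumours against cells 50.0% and 85.0% of 14111 genes, and for the difference between batches 0% and 1.00% of 12736 genes. False calls made up 5.10%, 11.4%, 2.26%, 2.17% and 0% of calls in these 5 simulations. The simulations drew genes independently and gave each gene the same spread in all libraries. In the real cultures 19.4% of 11013 genes differed more than 2-fold between the shHrs replicates of batch 1, against 1.25% between the shCTL replicates of batch 2. The simulated shares may therefore not hold for the real data. Alternatives were size factors of the RLE type, no filter on low counts, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, and fits with or without batch. Further alternatives for the tumours were the level of Xist as a covariate and, added after the results were seen, that of the pan-leukocyte or skeletal muscle list.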

Results

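B16F10 cells, a mouse melanoma line, were studied after knockdown of Hgs, the gene of the endosomal protein Hrs. Hrs is the part of the ESCRT-0 complex that gathers ubiquitinated membrane proteins for sorting into multivesicular endosomes. By its title, the series concerns immune evasion by tumours, protein homeostasis and activation of the interferon pathway. RNA was sequenced from cultured cells and from tumours that the same cells formed in immunocompetent mice, with an shRNA against Hgs (shHrs) or a scrambled shRNA (shCTL). The cultures formed 2 batches, each with 2 shHrs and 2 shCTL libraries, and the tumours formed 2 groups of 5. Total counts, in M (mega), were 18.6 to 25.3 M for shCTL and 18.5 to 21.8 M for shHrs cultures of batch 1, and 20.3 to 22.2 M for shCTL and 20.5 to 27.6 M for shHrs cultures of batch 2. In tumours they were 17.6 to 22.05 M for shCTL and 18.8 to 27.7 M for shHrs. The labels call the libraries biological repeats but do not say whether cultures of a batch were grown apart, so p-values for the cultures measure only the spread between these libraries, which may be technical.

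Hgs, on chromosome 11 from 120467635 to 120483979 of GRCm38 (mm10), was lower in each shHrs library than in each shCTL library of the same batch or tissue. In batch 1 it stood at 95.2 and 118 CPM in shCTL cultures (mean 107 ± 16.2, SD, n = 2) and at 36.7 and 30.1 CPM in shHrs cultures (33.4 ± 4.65, n = 2). In batch 2 it stood at 98.9 and 106 CPM in shCTL cultures (102 ± 4.68, n = 2) and at 44.5 and 40.5 CPM in shHrs cultures (42.5 ± 2.80, n = 2). Tumours held 94.0 to 110.3 CPM with shCTL (103 ± 7.18, n = 5) and 16.3 to 28.8 CPM with shHrs (21.4 ± 5.14, n = 5). The log2 fold change was -1.49 (SE 0.17) in the cultures of both batches and -2.28 (SE 0.16) in tumours. By edgeR the adjusted p was 0.000106 in tumours, 0.0268 in batch 2 and 0.0502 over both batches, just outside the threshold. Over both batches the adjusted p was 0.0275 by edgeR without batch 1 shHrs replicate 1, 0.0332 by limma voom and 7.0e-11 by DESeq2, within a range of 7.0e-11 to 0.375 over all alternatives. The call in batch 2 ended by edgeR without batch 2 shHrs replicate 1 (adjusted p = 0.117), shHrs replicate 2 (0.308), shCTL replicate 1 (0.177) or shCTL replicate 2 (0.194).

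**Figure D1:**
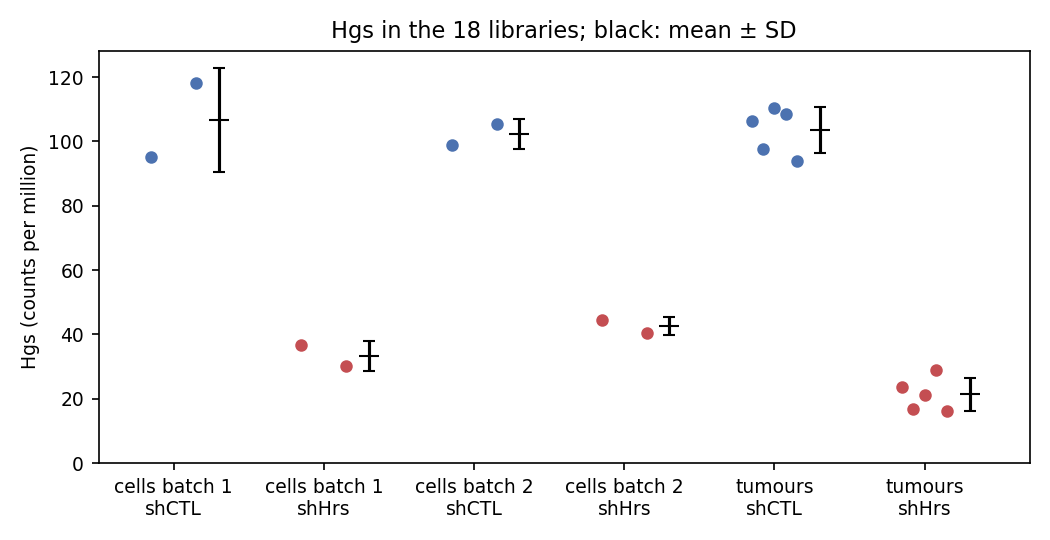
Hgs in CPM (vertical axis) in each of the 18 libraries, by group (horizontal axis). Points are libraries, and black marks give the mean and SD of each group. The highest shHrs library stands at 44.5 CPM and the lowest shCTL library at 94.0 CPM.

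Over both culture batches, genes that type I interferon induces against viruses rose as a list with Hrs knockdown by camera with a preset correlation. With an estimated correlation neither this list (adjusted p = 0.375) nor any other passed. Of the 42 tested genes, 40 had a positive log2 fold change, with a median of 1.72 between 4 shHrs and 4 shCTL libraries, although batch 1 shHrs replicate 1 stood at the level of the controls. The lists of interferon gamma response (median 1.18, 19 genes), MHC class I presentation (0.54, 15 genes) and nucleic acid sensing (0.22, 18 genes) rose too. So did the heat shock response (0.77, 19 genes) and the unfolded protein response (0.37, 24 genes). The proteasome rose by a median of 0.45, and its 31 subunits all had positive values. In batch 1 alone the medians were -0.05 for the proteasome, 0.06 for heat shock, 0.07 for MHC class I and -0.06 for nucleic acid sensing, and camera called none of them there (adjusted p = 0.410 to 0.894). Genes of cytosolic ribosomal proteins (0.30) and of the ESCRT machinery that acts with and after Hrs (0.14, 23 of 28 positive) rose as well. Cell cycle genes fell, with a median of -1.05 and 37 of 38 genes negative. So did hypoxia and glycolysis genes (-0.50), NF-kB targets (-0.59), pigmentation genes (-0.51) and the collagens and other fibroblast markers that the line expresses (-0.75). By batch, camera called the hypoxia, NF-kB and fibroblast lists lower in batch 1 but not in batch 2. Pigmentation genes had a positive median in batch 1, against -1.16 in batch 2. Camera called these 14 lists with adjusted p from 2.3e-21 to 0.0289, and with an estimated correlation their adjusted p was 0.375 to 0.708. Fry called 0 lists (lowest adjusted p = 0.117), while camera's unadjusted p was under 0.05 for 15 lists. The list of cholesterol synthesis, not called, had a median of 0.17 while camera's direction was down.

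Single genes did not pass over both batches. EdgeR called 0 of 12617 genes, with 1680 at an unadjusted p under 0.05, while limma voom called 5 genes, DESeq2 301, and edgeR with no filter on low counts 74. Adjusted over the list alone, 27 of 42 type I interferon genes, 9 of 19 interferon gamma genes and 5 of 19 heat shock genes passed as higher, and 5 of 28 hypoxia genes as lower. Trim25, a ubiquitin ligase of RNA sensing, had a log2 fold change of 2.36 (SE 0.28), Isg15, a ubiquitin-like protein, 3.93 (SE 0.89), Ifit1, which binds viral RNA, 3.04 (SE 0.63), and the chemokine Ccl5 3.45 (SE 0.83). Ankrd37, a target of hypoxia-inducible factor, had -2.27 (SE 0.29). Of the other genes fixed beforehand, Irf7 had 1.96 (SE 0.65), B2m 0.54 (SE 0.21), H2-K1 0.22 (SE 0.45), Cxcl10 0.79 (SE 1.06), Cd274 -0.10 (SE 0.33) and the chaperone Hspa5 1.19 (SE 0.55). Ddit3 and Atf3, transcription factors of stress, had -0.74 (SE 1.21) and 0.37 (SE 1.18), and Stam, Tsg101 and Vps4a of the ESCRT pathway 0.15 (SE 0.44), 0.02 (SE 0.20) and -0.06 (SE 0.26). Ifnb1, which encodes interferon beta itself, gave 1 count in the 8 cultures together and was not tested. EdgeR called 164 genes without batch 1 shHrs replicate 1 and 3 without batch 1 shCTL replicate 2. Without single libraries, camera's calls ended for ESCRT (without batch 2 shHrs 2, adjusted p = 0.177; batch 2 shCTL 1, 0.0930; batch 1 shCTL 2, 0.0557; batch 1 shHrs 2, 0.0756), nucleic acid sensing (batch 2 shHrs 2, 0.0831) and unfolded proteins (batch 1 shHrs 2, 0.0519). Camera's calls also ended for NF-kB targets (batch 1 shHrs 1, 0.412; batch 1 shCTL 2, 0.327), fibroblast markers (batch 1 shCTL 2, 0.107) and pigmentation (0.0653 to 0.925 without batch 1 shCTL 1 or shHrs 2 or batch 2 shHrs 1, shHrs 2 or shCTL 1).

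In batch 2, edgeR called 206 genes higher and 314 lower with shHrs than with shCTL, of 12897 tested, and interferon-induced genes were among those higher. Of the 206 and 314 genes, 77 and 191 had the same sign in batch 1. With 2 libraries per group, an effect of the knockdown could not be told from other differences between the cultures of batch 2. Oas1a, which makes the messenger that activates RNase L, went from 1.54 ± 0.49 to 45.6 ± 4.40 CPM (SD, n = 2 each), a log2 fold change of 4.85 (SE 0.50). Of 45 tested type I interferon genes, 19 rose (38 adjusted over the list alone) and 43 had positive values, with a median of 2.36. They included Oas1g (4.39, SE 0.65), Xaf1 (4.05, SE 0.58), Trim30a (3.68, SE 0.56), Samd9l (2.26, SE 0.28) and Bst2 (2.02, SE 0.29), which tethers budding virions. Zbp1, a sensor of left-handed nucleic acid, gave 104 counts with shHrs and 0 with shCTL, at least 32.5-fold higher against a floor of 3 counts over the shCTL group. Interferon gamma genes had a median of 2.45 with 4 of 20 raised (15 adjusted over the list alone). Among them were the GTPases Gbp3 (24.3-fold higher, SE 0.93 in log2), Igtp (4.11, SE 0.69) and Irgm1 (2.85, SE 0.36) and the feedback inhibitor Socs1 (2.69, SE 0.52). Antigen presentation by MHC class I had a median of 1.21 with 2 of 15 raised (12 adjusted over the list alone), Tapbp (1.40, SE 0.28) and Pdia3 (1.28, SE 0.27), both of the peptide-loading complex. In nucleic acid sensing (median 0.74) 2 of 19 genes rose (10 adjusted over the list alone), Zbp1 and the DNA exonuclease Trex1 (1.75, SE 0.34). Medians of the type I interferon, interferon gamma and nucleic acid lists were the same with genes of 3 counts or fewer in a group set at that floor. Irf7 (3.00, SE 0.85), H2-K1 (1.16, SE 0.41), Cd274 (-0.53, SE 0.41), Hspa5 (0.62, SE 0.72) and Ddit3 (-3.05, SE 0.80) did not pass in batch 2. Isg15 (4.79, SE 1.21), Ifit1 (3.42, SE 0.90), Ccl5 (3.67, SE 1.20) and B2m (0.93, SE 0.23) did not pass either, with adjusted p by edgeR of 0.0620, 0.0669, 0.0994 and 0.0598.

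By camera with a preset correlation, chaperone and proteasome genes rose as lists in batch 2 and cell division genes fell. With an estimated correlation the adjusted p was 0.558 for heat shock, 0.650 for the proteasome and 0.727 for the cell cycle. Of 19 heat shock genes, 10 rose (15 adjusted over the list alone), with a median of 1.39. They included Hspb1 (4.41, SE 0.89), Hspa1b (2.66, SE 0.40), Hspb8 (2.22, SE 0.34), Hsph1 (1.94, SE 0.29) and Hsp90aa1 (1.60, SE 0.28). All 31 proteasome subunits had positive values (median 0.86), of which 1 passed, Psmb3 (1.04, SE 0.22), and 28 adjusted over the list alone. Ribosomal protein genes had a median of 0.41 with 0 of 32 passing. Of 38 cell cycle genes, 16 fell (27 adjusted over the list alone), with a median of -1.70. Among them were the spindle genes Tpx2 (-2.37, SE 0.28), Kif11 (-2.89, SE 0.38) and Nusap1 (-3.01, SE 0.42) and the mitotic cyclin Ccnb1 (-2.09, SE 0.33). Genes of the integrated stress response had a median of -1.60 with 5 of 26 lowered (9 adjusted over the list alone). Among them were the glutathione-degrading Chac1 (-5.72, SE 0.91), the pseudokinase Trib3 (-4.88, SE 0.98), the amino acid transporter Slc7a5 (-2.11, SE 0.36) and Mthfd2 of mitochondrial folate metabolism (-2.06, SE 0.39). Pigmentation genes had a median of -1.16, with 1 of 18 lowered, Rab38 of melanosome transport (-1.39, SE 0.31). Among genes outside these lists, Nqo1, a quinone reductase, rose by 3.53 (SE 0.59). The receptor Gpr158 (-5.46, SE 1.15), the gasdermin Gsdmc (-4.00, SE 0.53), the ubiquitin ligase Rnf157 (-3.41, SE 0.36) and the spindle gene Aspm (-3.41, SE 0.65) fell. The helicase Pif1 (-3.53, SE 0.63), the regulator Aire (-3.42, SE 0.50) and the recombination gene Rad51b (-3.39, SE 0.57) fell too, as did Vegfa (-2.93, SE 0.59), the collagen gene Col1a2 (-2.55, SE 0.40) and Herpud1 (-2.95, SE 0.52). The hormone gene Stc1 fell from 60 to 2 counts. By edgeR the adjusted p of the genes named as changed in batch 2 ran from 0.0189 to 0.0495.

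Camera called 10 lists in batch 2, the 7 rising and 3 falling lists just described, with adjusted p from 5.4e-20 to 0.0156. With an estimated correlation 0 passed, with adjusted p from 0.558 to 0.890, and fry called nucleic acid sensing and heat shock (both 0.0316). Positions on GRCm38 were chromosome 5 from 120896256 to 120907521 for Oas1a, 11 from 72301629 to 72313733 for Xaf1 and 5 from 135887919 to 135889563 for Hspb1. They were chromosome 8 from 107388225 to 107403206 for Nqo1, 2 from 21367542 to 21830547 for Gpr158 and 15 from 63775968 to 63808759 for Gsdmc. The ESCRT list was not called in batch 2 (median 0.24, adjusted p by camera 0.0898), and of its 28 genes Mvb12b fell (-1.18, SE 0.24). Lists whose median and camera direction differed in sign in batch 2, none of them called, were the lysosome (0.00013, down), p53 targets (-0.09, up), chemokines (-0.16, up), MAPK feedback targets (-0.13, up), dendritic cell markers (-0.05, up) and immune checkpoints (-0.24, up). EdgeR called 0 genes without any single library of batch 2, 2705 without batch 1 shHrs replicate 1 and 2732 without batch 1 shHrs replicate 2, and 4303 in a fit of the 4 libraries of batch 2 alone. The pigmentation call ended without batch 2 shCTL replicate 1 (adjusted p by camera 0.0541) and the ribosomal call without batch 2 shHrs replicate 2 (0.0886).

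**Figure D2:**
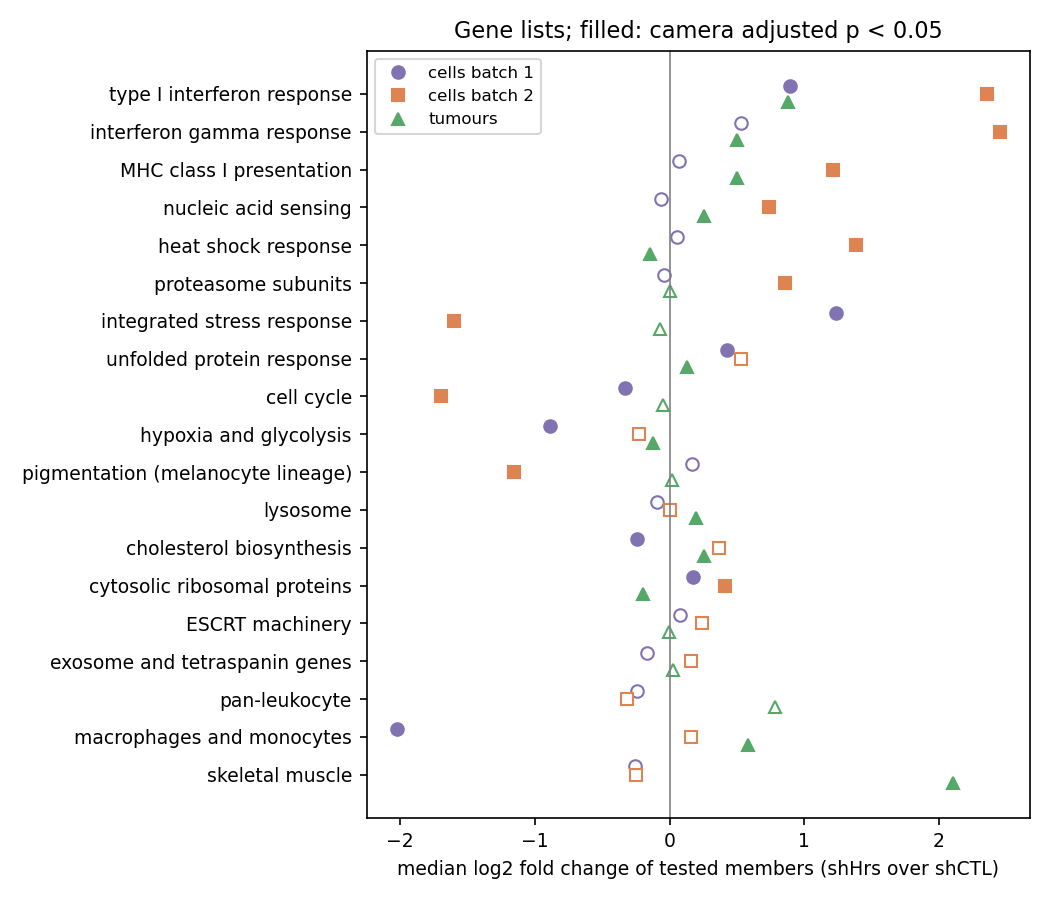
Median log2 fold change of the tested members of 19 gene lists (horizontal axis, shHrs over shCTL) in cells of batch 1 (circles), cells of batch 2 (squares) and tumours (triangles). Filled symbols passed camera with a preset correlation of 0.01, which 0 lists in these comparisons did with an estimated correlation. Type I interferon genes lie at 0.90, 2.36 and 0.88.

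In batch 1, camera with a preset correlation called genes of the integrated stress response higher and genes of hypoxia and glycolysis lower with Hrs knockdown. With an estimated correlation the adjusted p was 0.718 and 0.136. The higher stress level was in 1 of the 2 shHrs cultures, at a mean log2 CPM of 6.36 in replicate 1 and 8.63 in replicate 2, against 6.63 and 5.88 with shCTL. All 26 stress genes had positive values (median 1.24), among them Chac1 (2.39, SE 0.77) and Trib3 (1.88, SE 0.86), which lay below 0 in batch 2. Of 28 hypoxia genes, 24 were negative (median -0.89) and 13 fell adjusted over the list alone, among them the mitophagy receptor Bnip3 (-1.71, SE 0.28), the kinase Pdk1 (-1.40, SE 0.32) and the glycolytic enzyme Pgk1 (-0.98, SE 0.25). Type I interferon genes had a median of 0.90 with 40 of 45 positive, and their mean log2 CPM was 2.91 in shHrs replicate 1 and 4.53 in shHrs replicate 2, against 3.16 and 2.52 in the shCTL cultures. By camera the stress list (adjusted p = 3.4e-09), the hypoxia list (1.3e-14) and the interferon list (2.2e-06, and adjusted p = 0.815 with an estimated correlation) passed, and fry called the hypoxia list (0.0241). Camera also called the unfolded protein response (0.42), autophagy (0.27), p53 targets (0.34) and ribosomal proteins (0.17) upward. It called the cell cycle (-0.33), cholesterol synthesis (-0.24), NF-kB targets (-0.71), TGF-beta targets (-1.23), fibroblast (-1.17) and macrophage markers (-2.03, or -1.58 with a gene of few counts at its floor) downward, at adjusted p of 0.672 to 0.854 with an estimated correlation. The cultures are of B16F10 alone, so these markers stand for genes of the line and not for other cells. Of 25 macrophage markers tested in tumours, 5 were also tested in the fit of both culture batches. EdgeR called 0 of 12897 genes in batch 1, with 1210 at an unadjusted p under 0.05, while DESeq2 called 220, limma voom 0 and edgeR with no filter 438. Without batch 1 shHrs replicate 1 it called 1496 genes and without batch 1 shCTL replicate 1 it called 3. In batch 1 the MAPK, pigmentation, MHC class I and immediate early lists (0.0083, 0.16, 0.07 and 0.14) had a camera direction of down, and chemokines (-0.56) and proteasome subunits (-0.05) of up.

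The knockdown's effect differed between the batches for 20 genes. In 17 of them the effect in batch 2 lay above that in batch 1, a balance that DESeq2's calls (500 above and 480 below) did not share. Plat, the tissue plasminogen activator, went from 18.8 ± 10.3 to 1.63 ± 0.39 CPM in batch 1 and from 2.02 ± 0.41 to 6.93 ± 0.88 CPM in batch 2 (SD, n = 2 each). The chaperone Hspb7 went from 25.0 ± 18.9 to 6.82 ± 3.29 and from 4.66 ± 1.63 to 99.9 ± 0.69 CPM. Ndc80, of the kinetochore, went from 42.9 ± 4.37 to 52.2 ± 5.86 CPM in batch 1 and from 63.5 ± 9.43 to 8.40 ± 1.21 CPM in batch 2. Jdp2, a repressor of AP-1, went from 27.8 ± 7.34 to 48.7 ± 1.28 and from 59.9 ± 11.8 to 13.0 ± 0.43 CPM. By camera 11 lists differed, and type I interferon genes (median difference 1.72, adjusted p = 0.589 or more for every list with an estimated correlation) and integrated stress genes (-2.89) moved apart in opposite senses. Across 12128 genes, which are not independent replicates, Spearman's rho between the fold changes of the batches was -0.000925, and 77 of the 206 genes raised in batch 2 and 191 of the 314 lowered there had the same sign in batch 1. The count of 20 was 0 without any single library of batch 2 or without batch 1 shCTL replicate 2, 142 without batch 1 shCTL replicate 1, 635 without batch 1 shHrs replicate 2 and 1968 without batch 1 shHrs replicate 1.

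**Figure D3:**
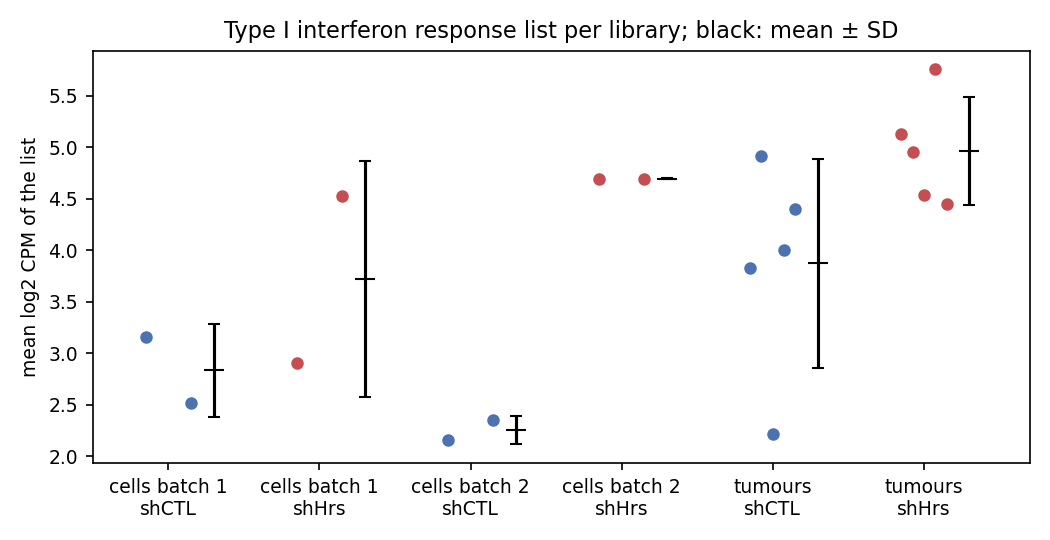
Mean log2 CPM of the tested type I interferon genes (vertical axis; 42 genes in cells, 46 in tumours) per library, by group (horizontal axis), with group means and SDs in black. Both batch 2 shHrs libraries lie at 4.70, the batch 1 shHrs libraries at 2.91 and 4.53, and the tumours between 2.22 and 5.76.

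In tumours, 31 of 13215 tested genes were higher and 41 lower with shHrs than with shCTL. No gene of the type I interferon list was among them. An effect of Hrs loss could not be told from other differences between the shHrs and shCTL cells that formed the tumours. Ndst3, an enzyme of heparan sulfate synthesis, rose most among the genes named by the fixed rule, from 0.84 ± 0.22 to 3.67 ± 0.95 CPM (SD, n = 5 each), a log2 fold change of 2.11 (SE 0.27). L1cam, a cell adhesion molecule of neurons, rose from 4.01 ± 1.99 to 15.1 ± 1.80 CPM (1.90, SE 0.30). Vwf, the von Willebrand factor of endothelial cells, rose from 38.1 ± 6.07 to 77.0 ± 9.52 CPM (1.01, SE 0.13). The list of endothelial markers was not called by camera, at a mean log2 CPM of 4.30 ± 0.34 in shHrs and 4.23 ± 0.22 in shCTL tumours. Map1a (1.44, SE 0.24), which binds microtubules, Tubb2a (1.01, SE 0.16), a tubulin, Tmod1 (1.31, SE 0.16), which caps actin filaments, the extracellular Adamtsl5 (1.32, SE 0.19) and Plekhb1 (1.03, SE 0.20) rose as well. The tetraspanin Cd9, found on exosomes, rose by 0.77 (SE 0.11) and S100b, a calcium-binding protein of melanocytes, by 0.84 (SE 0.13). Besides Hgs, the genes lowered most among those named by the rule were Shisa2 (-1.77, SE 0.32), the transcriptional cofactor Lmo1 (-1.59, SE 0.27), the polarity gene Pard6g (-1.24, SE 0.18) and the vesicle-priming gene Unc13b (-1.23, SE 0.18). They were followed by Podxl2 (-1.05, SE 0.19), the Wnt pathway repressor Tcf7l1 (-1.03, SE 0.15) and the matrix protein Efemp2 (-1.02, SE 0.20). For each of the 72 genes every shHrs tumour lay on one side of every shCTL tumour. Such a separation is given by chance for 0.794% of genes and was found for 537 of the 13215 tested. Positions on GRCm38 were chromosome 3 from 123526166 to 123690853 for Ndst3, X from 73853778 to 73896105 for L1cam, 6 from 125546774 to 125686679 for Vwf, 4 from 46038935 to 46116032 for Tmod1 and 7 from 109138572 to 109175207 for Lmo1.

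By edgeR the adjusted p of these tumour genes ran from 0.000106 for Hgs to 0.0469 for Efemp2. The count of 72 was 43 without shCTL replicate 1, 32 without shCTL replicate 3, 43 without shCTL replicate 5, 37 without shHrs replicate 1, 40 without shHrs replicate 2 and 158 without shHrs replicate 4, and DESeq2 called 549. It was 9 with the level of the skeletal muscle list as a covariate, where the calls of Hgs, Ndst3, Tmod1 and Vwf held and those of the other 12 named genes ended (adjusted p by edgeR 0.0541 to 0.182). The calls of Hgs, Ndst3, Adamtsl5, Tmod1, Vwf, Pard6g, Unc13b and Tcf7l1 held with each tumour left out. In a fit of all 18 libraries the calls of 9 of the 16 named genes ended, Pard6g, Unc13b, Vwf, Tubb2a, Plekhb1, Shisa2, Lmo1, Podxl2 and Efemp2 (adjusted p by edgeR 0.0645 to 0.305). Those of L1cam (adjusted p up to 0.0592, without shCTL 1 or shHrs 1), Tubb2a (0.0535, without shCTL 3 or shHrs 2), Map1a (0.0728, without shCTL 1, 2 or 3 or shHrs 3) and Lmo1 (0.0800, without shCTL 1, 3 or 5 or shHrs 1 or 5) ended in edgeR. The calls of Plekhb1 (0.132, without any tumour but shHrs 4), Shisa2 (0.115, without any but shHrs 1 or 4), Podxl2 (0.117, without any but shCTL 2 or shHrs 4) and Efemp2 (0.148, without any but shCTL 4 or shHrs 4) ended in edgeR more often.

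**Figure D4:**
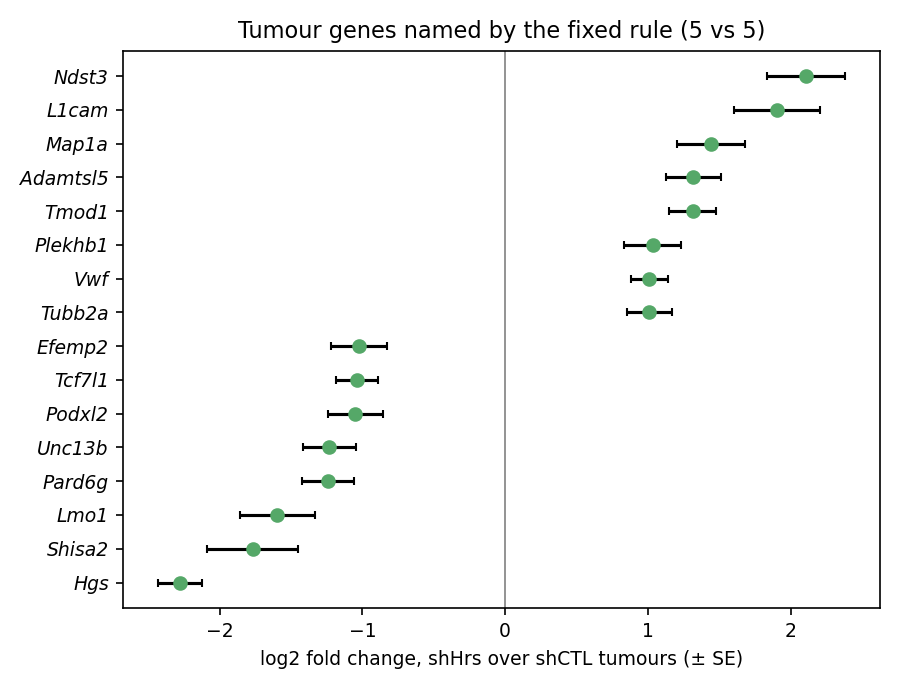
Log2 fold change in tumours (horizontal axis, shHrs over shCTL, bars give the SE) of Hgs and of the 8 rising and 7 other falling genes named by the fixed rule (vertical axis), 5 tumours per group. Values run from -2.28 for Hgs to 2.11 for Ndst3.

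By camera with a preset correlation, type I interferon, lysosome and skeletal muscle genes were higher as lists in shHrs tumours and ribosomal protein genes were lower. None of these 4 lists passed with an estimated correlation (adjusted p = 0.849 for each). All 46 tested type I interferon genes had positive values, with a median of 0.88, and 13 rose adjusted over the list alone, while 0 passed over all genes. Isg15 (1.70, SE 0.46), Ifit1 (1.36, SE 0.53) and Irf7 (1.37, SE 0.67) had adjusted p by edgeR of 0.127, 0.273 and 0.395. The mean log2 CPM of the list was 4.97 ± 0.52 in shHrs and 3.87 ± 1.02 in shCTL tumours (SD, n = 5 each), a difference of 1.09 with an exact permutation p of 0.0317 (adjusted p = 0.102 over 16 such tests). Beside the pan-leukocyte level the difference was 0.62 (permutation p = 0.0317), and beside the skeletal muscle level 0.29 (permutation p = 0.468). Of 33 lysosome genes 28 were positive (median 0.19) and 10 rose adjusted over the list alone. Among them were the glycoprotein Gpnmb (0.62, SE 0.14) and the sialidase Neu1 (0.35, SE 0.08). Neither Gpnmb nor Neu1 passed over all genes. The mean level of the lysosome list differed by 0.20 (exact permutation p = 0.0159, adjusted p = 0.102), by 0.14 beside the pan-leukocyte level (permutation p = 0.0397) and by 0.10 beside the muscle level (permutation p = 0.0952). Cholesterol synthesis had a median of 0.26 with 21 of 24 positive. Dhcr7, its last enzyme, rose adjusted over the list alone (0.41, SE 0.10) but did not pass over all genes. Camera also called the interferon gamma response (0.50, 31 of 32 positive), MHC class I presentation (0.50), nucleic acid sensing (0.26), chemokines (0.62, 16 of 18 positive), the unfolded protein response (0.13) and macrophage and monocyte markers (0.58, 22 of 25 positive) upward, each with adjusted p = 0.849 with an estimated correlation. Ribosomal protein genes (-0.20, 31 of 32 negative), the heat shock response (-0.14), hypoxia and glycolysis (-0.12) and MAPK feedback targets (-0.19), of which Etv1 (-0.65, SE 0.17) and Spry4 (-0.57, SE 0.16) fell adjusted over the list alone, were called downward. None of these lists passed with an estimated correlation (adjusted p = 0.849, and 0.913 for hypoxia). Etv1 and Spry4 did not pass over all genes.

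Camera's adjusted p for these 14 tumour lists ran from 4.2e-18 to 0.0374. Fry called 0 of them (lowest 0.560). Lists not called included ESCRT (median -0.0022, adjusted p by camera 0.627), exosome and tetraspanin genes (0.03, 0.209), the proteasome (0.0020, 0.776), the cell cycle (-0.05, 0.101) and pigmentation (0.02, 0.0967). Medians and camera directions differed in sign for ESCRT, proteasome, adipocyte (-0.20), fibroblast (-0.08) and NF-kB lists (-0.03) in tumours. Calls of the type I interferon, lysosome, cholesterol, muscle and ribosomal lists held by camera with each tumour left out. With the pan-leukocyte level as a covariate camera's calls ended for interferon gamma, MHC class I and hypoxia (adjusted p = 0.941 each), chemokines (0.778), nucleic acid sensing (0.256) and unfolded proteins (0.103), and the macrophage list turned in direction (0.587). The mean level of the interferon gamma list differed by 0.72 (exact permutation p = 0.452) and by 0.03 beside the pan-leukocyte level (permutation p = 0.921). Without shCTL replicate 3 or shHrs replicate 4, camera called 7 lists, and the calls ended for interferon gamma (adjusted p = 0.358 and 0.269), MHC class I (0.648 and 0.406, also 0.0748 without shHrs 1), nucleic acid sensing (0.116 and 0.406, also 0.0683 without shCTL 1), chemokines (0.148 and 0.162) and macrophage markers (0.301 and 0.213, also 0.0709 without shCTL 1). Camera's adjusted p rose to at most 0.144 for unfolded proteins (without shCTL 2 or 3 or shHrs 1, 2, 3 or 4), 0.151 for heat shock (shCTL 2 or 3 or shHrs 1, 3 or 5), 0.671 for hypoxia (shCTL 1, 3 or 5 or shHrs 1 or 4) and 0.0833 for MAPK targets (shCTL 1 or shHrs 1 or 4).

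Markers of other cell types varied between tumours. Of 15 skeletal muscle genes 14 were positive (median 2.10). Des, the intermediate filament of muscle, rose adjusted over the list alone (1.37, SE 0.34) but did not pass over all genes. The list's mean log2 CPM was 3.42 ± 1.79 in shHrs and 0.95 ± 1.89 in shCTL tumours (SD, n = 5 each; exact permutation p = 0.0714). Acta1, the actin of skeletal muscle, ranged from 8.52 to 256 CPM in shHrs and from 0.63 to 43.5 CPM in shCTL tumours. Of 12 pan-leukocyte genes 11 were positive (median 0.78, adjusted p by camera 0.0978), and the list's mean differed by 0.64 with an exact permutation p of 0.357. Ptprc (0.87, SE 0.70), the chemokines Cxcl9 (0.22, SE 0.77), Cxcl10 (0.82, SE 0.27) and Ccl5 (1.17, SE 0.51), Gzmb of cytotoxic cells (1.04, SE 0.98), B2m (0.50, SE 0.46), H2-K1 (0.17, SE 0.41) and the checkpoint ligand Cd274 (0.49, SE 0.39) did not pass in tumours. Nor did Hspa5 (0.25, SE 0.13), Ddit3 (-0.02, SE 0.28), Atf3 (-0.20, SE 0.45), Stam (0.10, SE 0.15), Tsg101 (-0.05, SE 0.07) and Vps4a (-0.04, SE 0.07). Cd8a, Prf1, Ifng and Ifnb1 lay below the filter on counts in each fit. Erythroid genes had too few members for camera, and 3 of 4 fell adjusted over the list alone. They were Alas2 (-3.39, SE 0.70), Hba-a2 (-3.73, SE 0.79) and Beta-s (-3.47, SE 0.76). None of the 3 passed over all genes. The mean log2 CPM of the erythroid list differed by -2.24 (exact permutation p = 0.0317, adjusted p = 0.102 over 16 such tests). Xist, which gave 2 to 14 counts per culture, stood at 31.6 ± 25.4 CPM in shHrs and 21.9 ± 15.1 CPM in shCTL tumours of female hosts, a log2 difference of 0.55 (n = 5 each, exact permutation p = 0.429).

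The effect of shHrs against shCTL in tumours differed from its mean in the cultures for 522 of 14458 genes tested by edgeR. It was higher in tumours for 307 and lower for 215. Chance could not be excluded for this count, since 7 of 40 labellings, the treatment's own among them, reached 522 (highest 1337). The mean effect in the cultures joined 2 batches whose fold changes had a Spearman's rho of -0.000925. Itga3, an integrin chain, went from 0.64 ± 0.40 to 3.73 ± 4.48 CPM in batch 1 and from 0.42 ± 0.13 to 8.94 ± 1.48 CPM in batch 2 (SD, n = 2 each), and from 8.34 ± 1.79 to 5.29 ± 1.33 CPM in tumours (n = 5 each). Heat shock genes (median difference -0.94, 9 of the list called), proteasome subunits (-0.50), type I interferon genes (-0.79), ribosomal proteins (-0.52), histone transcripts (-1.09) and unfolded protein genes (-0.31) had lower effects in tumours. Cell cycle (1.03, 17 called), pigmentation (0.54), hypoxia (0.23) and lysosome genes (0.18) had higher ones. Camera called these 10 lists, and with an estimated correlation the adjusted p was 0.185 to 0.994. The comparison of cells and tumours shared 0 called genes of 12128 tested in both, since edgeR called 0 in the cells, and DESeq2's calls shared 18. Batch 2 and tumours shared 2 lowered genes, Hgs and, seen only after the data were examined, Tead2 (-1.18, SE 0.24 in batch 2 and -0.68, SE 0.12 in tumours), a transcription factor of the Hippo pathway, against 1.03 expected of independent calls. They shared 0 raised genes against 0.458 expected. Spearman's rho of fold changes across genes was 0.0931 between cells and tumours and 0.128 between batch 2 and tumours. The count of 522 was 125 without batch 2 shHrs replicate 2, 2194 without batch 1 shHrs replicate 1, 1277 without batch 1 shCTL replicate 2 and 173 to 337 without batch 2 shCTL 1 or 2, batch 1 shCTL 1, tumour shCTL 1, 2, 3 or 4 or tumour shHrs 1, 2, 3 or 5.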

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

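Of the tests below, the splits of the samples and the test for pieces of muscle were fixed before their result was seen, while those of the interferon list beside leukocyte and muscle markers, of batch 1 shHrs replicate 1 and of a chance arrangement of muscle were chosen after the result was seen.

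Type I interferon genes stood higher in shHrs than in shCTL tumours as a list, by 1.09 log2 CPM (5 against 5, exact permutation p = 0.0317). More leukocyte RNA in the shHrs tumours would leave little difference beside the pan-leukocyte level if that level followed leukocyte content closely. A difference of 0.6184 (SE 0.206) remained, with a permutation p of 0.0317 (adjusted p = 0.102 over 16 tests). This could not exclude leukocyte RNA as the whole cause or a part. The level may follow leukocyte content loosely, as 4 of its 12 genes were also tested in the cultures. More muscle tissue could account for the difference, since 0.2897 remained beside the skeletal muscle level, with an SE of 0.462 and a permutation p of 0.468, and muscle differed along with the treatment. The biological explanation, an effect of Hrs knockdown on the tumour cells, was set against this by the cultures, where the list's median was 1.72 over both batches and 0.90 and 2.36 within them. Over both batches, though, the list did not pass camera with an estimated correlation (adjusted p = 0.375), and batch 1 shHrs replicate 1 stood at the level of the controls. Muscle content and knockdown could not be separated with 10 tumours.

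Batch 1 shHrs replicate 1 stood at 2.91 in mean log2 CPM of type I interferon genes, between the 2 shCTL cultures of its batch at 2.52 and 3.16, while the other 3 shHrs cultures stood at 4.53 to 4.70. A control culture under an shHrs label was not likely, because its Hgs level was 36.71 CPM against 95.23 CPM in the lowest shCTL culture. A weaker knockdown stayed open, since within batch 1 this culture had more Hgs RNA than shHrs replicate 2 (30.1 CPM), and the 2 shHrs cultures with more Hgs RNA, up to 44.5 CPM, and a high list level were of batch 2. The 2 shHrs cultures of batch 1 also differed more than 2-fold from each other in 2142 of 11013 genes (19.4%), against 272 genes (2.47%) for those of batch 2. No biological explanation was tested.

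Skeletal muscle genes stood higher in shHrs tumours by 2.48 log2 CPM. Pieces of muscle carried along with some tumours might account for it, since the median Pearson correlation between pairs of the 15 genes over the 10 tumours was 0.9029, as shared tissue content would give. A chance arrangement of muscle content over 10 tumours could not be excluded, with an exact permutation p of 0.07143. Of the 72 genes called in tumours 0 were in the muscle list, but its genes varied widely within each group, so this says little about muscle's part in the calls. With the muscle level as a covariate, edgeR called 9 genes. No biological explanation was tested.

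Other splits of the samples into groups of the same size were fitted for 5 counts, and the numbers below include the treatment's own split. For the tumours and for tumours against cells, the other splits were a random draw of those possible. In the cultures the treatment called 0 genes, a count that any split reaches (34 of 34), so this comparison says nothing about chance. The split that put batch 1 shCTL replicate 2 with batch 1 shHrs replicate 2 and both batch 2 shHrs cultures called 178, which points to a structure of the samples. Within batch 1 it set the replicate 2 cultures against those of replicate 1. With the replicate number as a block, edgeR called 0 genes for the treatment in the cultures. For lists in the cultures 10 of 34 splits reached the 14 of the treatment (highest 20). In tumours 1 of 100 splits, that of the treatment itself, reached its 72 genes, and the highest other split called 51. That sets the count apart from the splits drawn, but cannot tell the knockdown from other differences between shHrs and shCTL cells. For lists in tumours 61 of 100 splits reached 14 (highest 28), and for tumours against cells 7 of 40 reached 522 (highest 1337). Chance could thus not be excluded for the counts of lists in cultures and tumours or for the count of tumours against cells.

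Of 140 groups of values tested, 15 held a tumour far from the other 4 of its group, where chance gives about 1 in 20. That rate holds for normally spread values, which CPM of single genes need not be. Most flags fell on shHrs replicate 4, so the 15 are not independent and their excess was not tested. Tumour shHrs replicate 4 stood apart in Xist (75.56 CPM), Adamtsl5 (32.5 CPM), Irf7 (96.45 CPM), Cxcl9 (72.62 CPM), Cxcl10 (199.9 CPM), Gzmb (5.832 CPM) and Ptprc (30.2 CPM). It also stood apart in mean log2 CPM of the nucleic acid sensing (4.872), chemokine (3.947), NF-kB (3.756) and pan-leukocyte lists (4.826). Tumour shCTL replicate 1 stood apart in Atf3 (83.61 CPM) and in histone transcripts (1.951 in mean log2 CPM). Tumour shHrs replicate 1 stood apart in L1cam (18.27 CPM) and Shisa2 (1.625 CPM).

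The effect of knockdown differed between the culture batches for 20 genes by edgeR's test of the interaction. The log2 difference, batch 2 over batch 1, was 6.414 for Lims2, 6.244 for Hspb7, 6.098 for Trim16, 5.262 for Plat, -3.234 for Ndc80 and -3.045 for Jdp2. By camera's test of the interaction the median log2 difference was 1.721 for type I interferon genes, 1.569 for interferon gamma genes, 1.045 for MHC class I, 0.7537 for nucleic acid sensing, 1.331 for heat shock, 0.9535 for the proteasome and 0.3968 for cholesterol synthesis. It was -2.888 for the integrated stress response, -1.286 for the cell cycle, 0.8883 for hypoxia and 1.061 for TGF-beta targets, and none of these 11 passed with an estimated correlation (adjusted p = 0.589 to 0.842).

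The effect in tumours differed from that in the cultures for 522 genes by edgeR's test of the difference. The log2 difference, tumours over cultures, was 3.671 for Psd3, 3.629 for Stc1, 3.501 for Nid2, -5.37 for Mlip, -5.257 for Angptl4, -4.441 for Arhgef5 and -4.184 for Itga3. These fitted values are not exact where a culture group gave few counts. The shCTL cultures gave 0 counts of Mlip in both batches, 9 and 1 of Angptl4 and 1 and 2 of Arhgef5. The shHrs cultures gave 1 count of Psd3 in batch 1 and 2 counts of Stc1 in batch 2. With each group held at no less than 3 counts, the difference was -1.81 for Mlip, -4.72 for Angptl4, -3.60 for Arhgef5, 3.13 for Psd3, 3.52 for Stc1 and 1.04 for Nid2. The cultures together gave 14 counts of Nid2, and its call ended in 15 of 18 fits with 1 library left out. By camera the median log2 difference was -0.7861 for type I interferon genes, -0.3103 for unfolded proteins, -0.9409 for heat shock, -0.5002 for the proteasome, 0.1813 for the lysosome and 1.028 for the cell cycle. It was 0.2289 for hypoxia, 0.5409 for pigmentation, -0.5228 for ribosomal proteins and -1.094 for histone transcripts, with adjusted p of 0.185 to 0.994 with an estimated correlation.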

How the results depend on the processing

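The covariates for muscle and leukocytes, the batch by treatment term, the fits of a single batch and the fits without the tumours lowest and highest in leukocyte markers were chosen after the results were seen. Each culture group had 2 libraries, so a fit without 1 of them left a lone library that was assumed to vary like the other groups. At this depth Ifnb1, Ifng, Cd8a and Prf1 fell below the filter on counts (minimum count 10) and stayed untested. The direction of Hgs was kept by every alternative run for cells, batch 2 and tumours. Calls of the camera test rested on the preset correlation, as 0 lists passed in cells, batch 2 or tumours with an estimated correlation. The replicate numbers were not taken as pairs. In tumours 1 of 5 shHrs libraries correlated best with its own number, and in the cultures, where 2 replicates give 1 value per batch, the correlation between equal numbers was 0.191 in batch 1 and 0.0231 in batch 2. The numbers as a block gave 6 genes in tumours, 20 lists in tumours, 373 genes for tumours against cells and -1.49 for Hgs in cells (adjusted p by edgeR 0.271), and with it the calls of 13 of the 16 named tumour genes ended. Where no reason is given, the cause was not tested.

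Over both culture batches edgeR called 0 genes, and 74 with no filter, 301 with DESeq2, 5 with limma voom, 2136 with all 18 libraries in 1 fit, 3 without a batch term, 38 with a batch by treatment term and 0 to 164 with 1 library left out. The log2 fold change of Hgs was -1.47 with no filter, -1.462 with DESeq2, -1.484 with limma voom, -1.46 with all 18 libraries, -1.477 without a batch term, -1.487 with the batch by treatment term and -1.55 to -1.393 with 1 library left out. Batch 1 gave 438 genes with no filter, 220 with DESeq2 and 0 to 1496 with 1 library left out. Batch 2 gave 2224 with no filter, 1988 with DESeq2, 4303 from its 4 libraries alone and 0 to 2732 with 1 left out. The difference between batches gave 1311 with no filter, 980 with DESeq2, 13 with limma voom and 0 to 1968 with 1 left out. Tumours gave 549 genes with DESeq2, 6 with the block, 29 with all 18 libraries, 276 with quality weights, 9 with muscle as a covariate, 18 at 2-fold or more and 32 to 158 with 1 left out. Tumours against cells gave 1410 with DESeq2 and 125 to 2194 with 1 left out. Genes shared by cells and tumours numbered 18 with DESeq2, 1 with no filter and 0 to 5 with 1 left out. Called lists with an estimated correlation, fry and 1 library left out were 0, 0 and 12 to 17 in cells, 0, 2 and 9 to 12 in batch 2, and 0, 0 and 7 to 18 in tumours. The Xist difference was 0.17 to 0.84 with 1 tumour left out.

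The sign turned for some genes. With 1 library left out, log2 fold changes over both batches ran from -0.1255 to 0.6366 for H2-K1, -0.3566 to 0.09492 for Cd274, -0.9509 to 1.299 for Cxcl10, -1.831 to 0.2921 for Ddit3, -1.323 to 1.226 for Atf3, -0.4091 to 0.4297 for Stam, -0.09426 to 0.1499 for Tsg101 and -0.2036 to 0.1763 for Vps4a. In batch 2 they ran from -0.6601 to 0.7293 for Cxcl10 and -0.007598 to 0.3931 for Tsg101, and in tumours from -0.1843 to 0.3666 for H2-K1, -0.6123 to 0.7411 for Cxcl9, -0.4773 to 1.389 for Gzmb, -0.2266 to 0.2871 for Ddit3 and -0.4022 to 0.5613 for Atf3. With limma voom Atf3 was -0.1548 in cells and 0.08452 in tumours, Cxcl10 0.01367 in batch 2 and Ddit3 0.03731 in tumours. With the block Atf3 was -0.482 and Tsg101 -0.0003327 in cells, and Ddit3 0.04258 and Atf3 0.148 in tumours. In tumours with Xist as a covariate H2-K1 was -0.1775, Cxcl9 -0.4056, Gzmb -0.129, Ddit3 0.1531 and Atf3 0.2247, and with quality weights Cxcl9 -0.0272, Ddit3 0.1344 and Atf3 0.2648. With leukocytes as a covariate H2-K1 was -0.2644, Cxcl9 -0.5079, Gzmb -0.2346, Ddit3 0.07752, Atf3 0.01938 and Tsg101 0.004334. With muscle as a covariate Irf7 was -0.1546, B2m -0.2188, H2-K1 -0.4872, Cd274 -0.255, Cxcl9 -0.887, Gzmb -1.042, Ptprc -0.4473, Ddit3 0.09245, Atf3 0.21 and Tsg101 0.01867. Without the tumours lowest and highest in leukocyte markers B2m was -0.05188, H2-K1 -0.4195, Cd274 -0.08175, Cxcl9 -0.9174, Gzmb -0.7867 and Ptprc -0.1682, and camera's adjusted p, with the direction turned, was 0.07493 for interferon gamma, 0.1918 for MHC class I, 0.857 for hypoxia and 0.5577 for macrophages. In the same fit the calls of 4 further lists ended, with adjusted p of 0.0517 for MAPK targets, 0.117 for unfolded proteins, 0.856 for nucleic acid sensing and 0.866 for chemokines. With leukocytes as a covariate it was 0.5874 for macrophages, with the direction turned.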
